A study of Mus musculus with 32 samples.

How the data were processed

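RNA from 32 samples of mouse XEN cells in 12 groups was made into Smart-seq2 libraries, which select polyadenylated RNA and keep no strand, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.4, HISAT2 2.2.0, StringTie 2.1.1 and the mouse build mm9, without saying which step used which setting. How reads were assigned to alleles is not given in the sources used here.

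The authors deposited 4 tables of X-linked genes with FPKM values (fragments scaled by transcript length and sequencing total) for Xa and Xi, in 24 columns, 1 for each group and allele. Per the file headers, the columns are merged over the samples of a group, so the planned limma test and replicate-wise checks could not be run. Differences are given as the authors' merged values. WT, XistpA, XRR_KO and XRRa_KO share a table, the XRRb and XRRc lines share another, and the Rad21 and Ctcf groups have 1 table each. The Ctcf table's columns name the treatment only and were matched to the Ctcf samples by elimination. Levels were compared within a table, and across tables only as Xi shares.

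FPKM carries no read total. Low Xi values below 1 FPKM were searched for a common step between columns, and at most 4 genes shared a ratio, so the depth is unknown and no interval is given. A value of 0 can be a failed estimate, because genes such as Uxt or Prickle3 were listed at 0 on both alleles in single columns. Such genes are described as listed at 0.

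Genes were tested when their Xa plus Xi FPKM averaged 1 or more over the columns of their table, which left 270, 261, 247 and 277 genes. Changes were computed as the difference of log2(FPKM + 0.5), and a change of 1 or more was the rule for "rose" and "fell". Named genes were, per comparison, the 8 largest rises and 8 largest falls on Xi and the 4 largest of each on Xa that met that size, plus Xist, Tsix, Rlim, Kdm6a, Kdm5c, Eif2s3x, Ddx3x and 4933407K13Rik, and 2 to 4 members of a described gene list. Other genes named were chosen after their values were seen. The 11 gene lists, the comparisons and most alternatives were fixed before the data were examined. A list's median was placed among 10000 random lists of the same size, matched in 5 bins of Xa plus Xi FPKM and not on the Xi level. Percentiles were computed for each list, allele and comparison, so some are extreme by chance, and Xi medians near 0 carry little information.

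Gene order came from RefSeq genes of GRCm38.p6, another build than the authors', so no coordinate is printed. It placed 999 of 1006 listed genes. Planned windows in megabases around Xist were not run for that reason and were replaced by the 30 nearest tested genes. Near-identical copies were found by aligning GENCODE M21 transcripts of the X to those of other chromosomes with minimap2 2.31, at 95% identity over 50% of the length or more. Of 304 tested genes 300 had a transcript, and 22 had such a copy. Genes without a transcript could not be checked and were counted as having no copy.

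Overlaps between groups that share the WT column were set beside the count for independent lists and beside 1000 simulated pairs without effect. The spread in those pairs was taken from XRRb_XaKO against XRRc_XaKO, which belong to another table than WT. Alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 5 FPKM, columns scaled to equal median Xa FPKM, changes centred on the median Xa change (added after the data were seen), share rules of 5% and 20%, and leaving out escape genes. The calls were tested on simulated data for XistpA against WT on Xi, with 40 of 268 genes raised and the spread taken from XRRb_XaKO against XRRc_XaKO. At a log2 change of 1.5, 98.5% of raised genes were recovered with 0.80 false calls on average. That spread comes from 1 pair of columns and may be too small for other pairs. The 178 genes listed at 0 on Xi in WT were given no spread. Their recovery was certain and false calls among them were impossible, so the simulation does not test rises from a listed 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.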

Results

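The data describe expression of X-linked genes in mouse XEN cells, stem cell lines of the extraembryonic endoderm, from a cross of 129S1/SvImj with JF1/Ms. Sequence differences between the parental strains let the authors assign expression to the active X (Xa) or the inactive X (Xi). The labels name 32 RNA samples in 12 groups. These are 3 WT, 4 XistpA, 2 XRR_KO and 3 XRRa_KO samples, 2 each of XRRb_XaKO, XRRb_XiKO, XRRc_XaKO and XRRc_XiKO, 4 each of Rad21 degron with DMSO or dTAG, and 2 each of Ctcf degron with DMSO or dTAG. The Rad21 samples of each treatment came from 2 clones, which the merged columns pool. dTAG is a small molecule that triggers degradation of a tagged protein, and the Ctcf treatment lasted 48 h. Each group entered the 4 tables as 1 merged FPKM value per gene and allele, so no difference below has a replicate check, no SD or p-value is given, and the sequencing depth is unknown. "Rose" and "fell" mean a log2(FPKM + 0.5) change of 1 or more, a scale that understates changes of low genes.

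In WT cells most X-linked genes were listed at or near 0 on Xi. Of 270 tested genes, 178 were listed at 0 on Xi, and 33 genes (12.2%) had an Xi share of 10% or more of their Xa plus Xi FPKM. Xist, the noncoding RNA that coats the inactive X, stood at 15.5 FPKM on Xi and 0.034 FPKM on Xa, a share of 99.8%. Known escape genes had the next highest shares. Eif2s3x, a translation initiation factor subunit, had 20.0 FPKM on Xi (41.5%), the RNA helicase Ddx3x had 45.2 FPKM (35.6%), and the histone demethylase Kdm5c had 0.763 FPKM (26.0%). Kdm6a, another histone demethylase, was listed at 0 on Xi in all 12 groups. Rps4x, a ribosomal protein gene, made up 60.8% of the Xi FPKM of tested genes, but it has near-identical copies on other chromosomes and its value is uncertain. Tsix, antisense to Xist, was listed at 31.2 FPKM on Xi and 0 on Xa. The libraries were unstranded, so its reads cannot be told apart from those of Xist.

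The genes with Xi expression were largely shared between control groups. Of 233 genes tested in all 4 tables, 26 had a share of 10% or more in each of the 5 control groups, and 196 were below 10% in every one. The tables were made separately, so only shares were set side by side. Among the 26 were Mmgt1 (41.8% in WT), Wdr45 (40.5%), Ndufa1, a subunit of respiratory complex I (33.4%), and the transcription factor Tfe3 (29.4%).

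XistpA was compared with WT to see how silencing stood in cells of that name, which the labels do not explain. Xist and Tsix were both listed at 0 FPKM on Xi in XistpA, against 15.5 and 31.2 FPKM in WT. On Xi, 33 of 270 genes rose and 4 fell. In this and the other comparisons with WT, the 178 genes listed at 0 on Xi in WT could rise but not fall. On Xa, 3 rose and 9 fell, and the median Xa change was -0.02. The largest Xi rise was 3830403N18Rik, from 0.249 to 91.8 FPKM (log2 change 6.95). The glycolytic enzyme gene Pgk1 went from 0.352 to 37.1 FPKM (5.46) and Eda2r from 0.391 to 31.2 FPKM (5.15). The prefoldin subunit gene Vbp1 went from 0.123 to 20.2 FPKM (5.05), and the respiratory complex IV subunit gene Cox7b from 0.029 to 15.4 FPKM (4.91). Morf4l2, a subunit of histone acetyltransferase complexes, rose from 4.46 to 146 FPKM, Stard8 rose by 4.31 and the mitophagy receptor gene Fundc1 by 4.20. Pgk1 and Morf4l2 have near-identical copies elsewhere and are uncertain. Besides Xist and Tsix, Ccdc22 and Bex2 fell on Xi, from 2.39 to 0.743 FPKM and from 0.569 to 0.034 FPKM.

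The risen genes reached a median Xi share of 35.8%, from 0.19% in WT, while their median Xa change was -0.10. Genes at an Xi share of 10% or more numbered 55 in XistpA against 33 in WT. The summed Xi share without Xist and Tsix was 17.6% against 9.10%. Also without Rps4x, whose value is uncertain, the summed share was 9.87% against 4.04%. The median share over all tested genes stayed near 0 (0.029%), and 193 genes were below 1%. On Xa, Xlr, Drp2 and Armcx1 rose (1.19, 1.17 and 1.14), and Rnf128 and Tspan7 fell (-1.81 and -1.43), as did Itm2a, from 1.23 to 0.070 FPKM. Nkrf was listed at 0 on both alleles in XistpA and at 4.92 FPKM on Xa in WT.

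**Figure D1:**
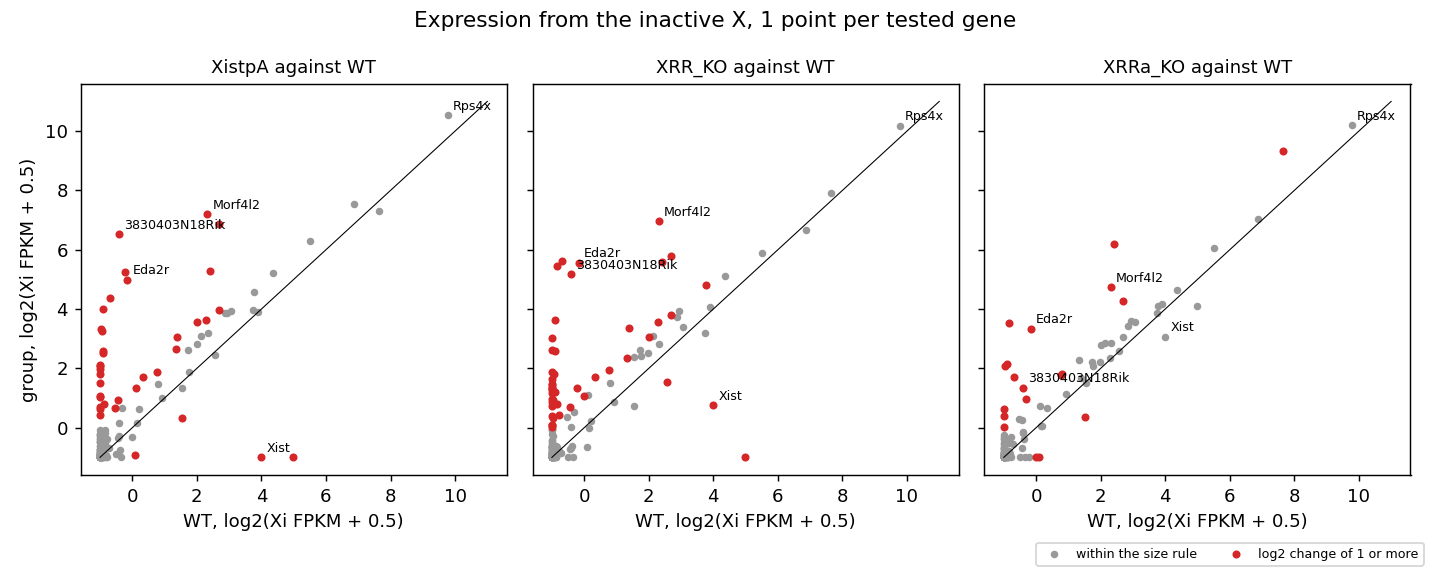
Each point is a tested gene, with log2(Xi FPKM + 0.5) in WT on the horizontal axis and in XistpA, XRR_KO or XRRa_KO on the vertical axis; red points changed by a log2 of 1 or more and the line marks equality. On Xi 33, 43 and 16 genes rose, many of them from the floor at the left edge, while Xist lies below the line in each panel.

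The fixed gene lists moved unevenly in XistpA. Of 9 tested escape genes, 3 rose on Xi (1810030O07Rik, Utp14a and Kdm5c, by 1.56, 1.30 and 1.37) and only Xist fell. The median of the 8 other than Xist was 0.81, at the 98.1st percentile of 10000 random lists matched on Xa plus Xi expression. Most genes in such lists are at or near 0 on Xi, so the percentile does not set escape genes apart from other genes expressed on Xi. The 29 genes with 1 FPKM or more on Xi in both columns, escape genes among them, had a median change of 0.87. Of 39 housekeeping genes, 3 rose on Xi (Pgk1, Cox7b and the lysosomal membrane gene Lamp2), with a median at the 23.5th percentile. Of 18 genes with extraembryonic roles, Cited1, a transcriptional coregulator, rose from 5.96 to 116 FPKM on Xi, Tceal8 rose by 2.86 and Bex1 went from a listed 0 to 0.849 FPKM. Bex2 fell, and the list's Xi median lay at the 11.9th percentile. On Xa its median was -0.17, at the 1.79th percentile, with Xlr4a and Gpc3 past the size rule (-1.41 and -1.14). Of 30 chromatin and transcription genes, Morf4l2 and Kdm5c rose on Xi (median at the 45.8th percentile). The X inactivation centre list had an Xi median of only -0.033, at the 0.02nd percentile. Xist and Tsix were the members that fell, and the other 6 of 8 stayed within the size rule.

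XRR_KO, given as 2 clones, was also compared with WT. Xist on Xi fell from 15.5 to 1.18 FPKM (-3.25), and Tsix was listed at 0 on Xi. On Xi 43 genes rose and 3 fell (Tsix, Xist and the RNA methyltransferase gene Ftsj1, the last by -1.02). The largest rises were the ribosomal protein gene Rpl36a, from 0.057 to 43.4 FPKM (6.30, with near-identical copies elsewhere), Vbp1 to 48.3 FPKM (6.29), Eda2r to 46.7 FPKM (5.73) and 3830403N18Rik to 35.6 FPKM (5.59). Morf4l2, Cox7b and Stard8 rose by 4.66, 4.54 and 4.01, and Lamp2 went from a listed 0 to 5.70 FPKM. Risen genes reached a median Xi share of 29.5%, with a median Xa change of -0.27. The number of genes at 10% or more was 58, and the summed share was 18.9%.

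On Xa in XRR_KO, 3 genes rose and 10 fell, with a median Xa change of -0.19. At equal median Xa FPKM, the counts were 6 and 7, and centred on the median Xa change 7 and 4. Both move all genes alike and so set this balance. Itm2a and Amer1 rose (1.27 and 1.05), Timp1, an inhibitor of metalloproteinases, and Mtcp1 fell (-1.87 and -1.46). Xlr3a was listed at 0 on both alleles against 138 FPKM on Xa in WT, and Xlr4a at 0 against 1.96 FPKM. Of 39 housekeeping genes, 5 rose on Xi, among them Rpl36a, Cox7b, Lamp2 and Atp6ap2, and 3 fell on Xa (Atp6ap1, Gla and Timm8a1, by -1.18, -1.11 and -1.01). Of 18 extraembryonic genes, 4 rose on Xi, with Tceal8 at 47.4 FPKM (3.17), Cited1 at 54.9 FPKM (3.10), Trap1a at 1.34 FPKM from a listed 0, and Amot (1.31). Among 30 chromatin genes, Morf4l2 and Kdm5c rose on Xi, and no member passed the size rule on Xa although the list's Xa median of 0.13 lay at the 99.6th percentile. Escape genes other than Xist had a median Xi change of 0.57 (91.6th percentile), with Kdm5c, Utp14a and 1810030O07Rik past the size rule. The 31 genes with 1 FPKM or more on Xi in both columns had a median of 0.77.

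XRRa_KO was closer to WT. Xist was at 7.86 FPKM on Xi (-0.94) and Tsix at 16.5 FPKM (-0.90), neither past the size rule. On Xi 16 genes rose and 3 fell, and on Xa 1 rose (Timp1, 1.75) and 1 fell (Armcx1, -1.90). The leading Xi rises were Rpl36a from 0.057 to 11.1 FPKM (4.38), Tceal8 from 4.81 to 71.9 FPKM (3.77), Eda2r to 9.56 FPKM (3.50), Mum1l1 to 3.93 FPKM (3.05), Sh3bgrl to 3.73 FPKM (3.05), Morf4l2 to 26.3 FPKM (2.44), Vbp1 to 2.80 FPKM (2.40) and 3830403N18Rik to 2.05 FPKM (1.77). Ccdc22 fell by -1.17, and Bex2 and Gm5643 were listed at 0 on Xi against 0.569 and 0.504 FPKM. Risen genes reached a median Xi share of 14.5%. Of 18 extraembryonic genes, Tceal8, Wbp5 (1.70) and Cited1 (1.59) rose on Xi. No gene of the fixed escape list passed the size rule on Xi, while the median of the 8 other than Xist was 0.31 (98.3rd percentile). The 31 genes with 1 FPKM or more on Xi in both columns had a median of 0.42. Genes at a share of 10% or more numbered 43.

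The 3 comparisons share the WT column, so part of any overlap can come from it. Of 268 genes without Xist and Tsix, 27 rose in both XistpA and XRR_KO, where independent lists would share 5.29 and simulated groups without effects shared a mean of 3.35 and at most 10. The covariance of their changes was 0.943 against a simulated 0.140. The simulated spread came from XRRb_XaKO against XRRc_XaKO and may be too small for the columns compared here. Taking a share gain of 10 points or more with a different control for each (WT for XistpA, XRRc_XaKO for XRR_KO), 29 genes gained in both, where independence gives 6.07. XRRa_KO shared 10 rises with XistpA, no more than the highest simulated count, with a correlation of 0.537 against a simulated 0.498 and a covariance of 0.357 against 0.140, and 13 with XRR_KO (correlation 0.717, covariance 0.474). With different controls, XistpA and XRRa_KO shared 12 share gains (XRRa_KO against XRRc_XaKO, 2.49 for independent lists) or 13 (XistpA against XRRc_XaKO, 2.38), and XRR_KO and XRRa_KO shared 13 (2.86) or 14 (2.73). These counts exceed independence without a shared WT column, although genes differ in how readily their Xi share varies. Among the 10 genes that rose in all 3 groups were Eda2r, 3830403N18Rik, Morf4l2, Cited1 and Mum1l1. Directly compared, Xi values were higher by the size rule for 16 genes in XRR_KO and for 10 genes in XistpA.

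**Figure D2:**
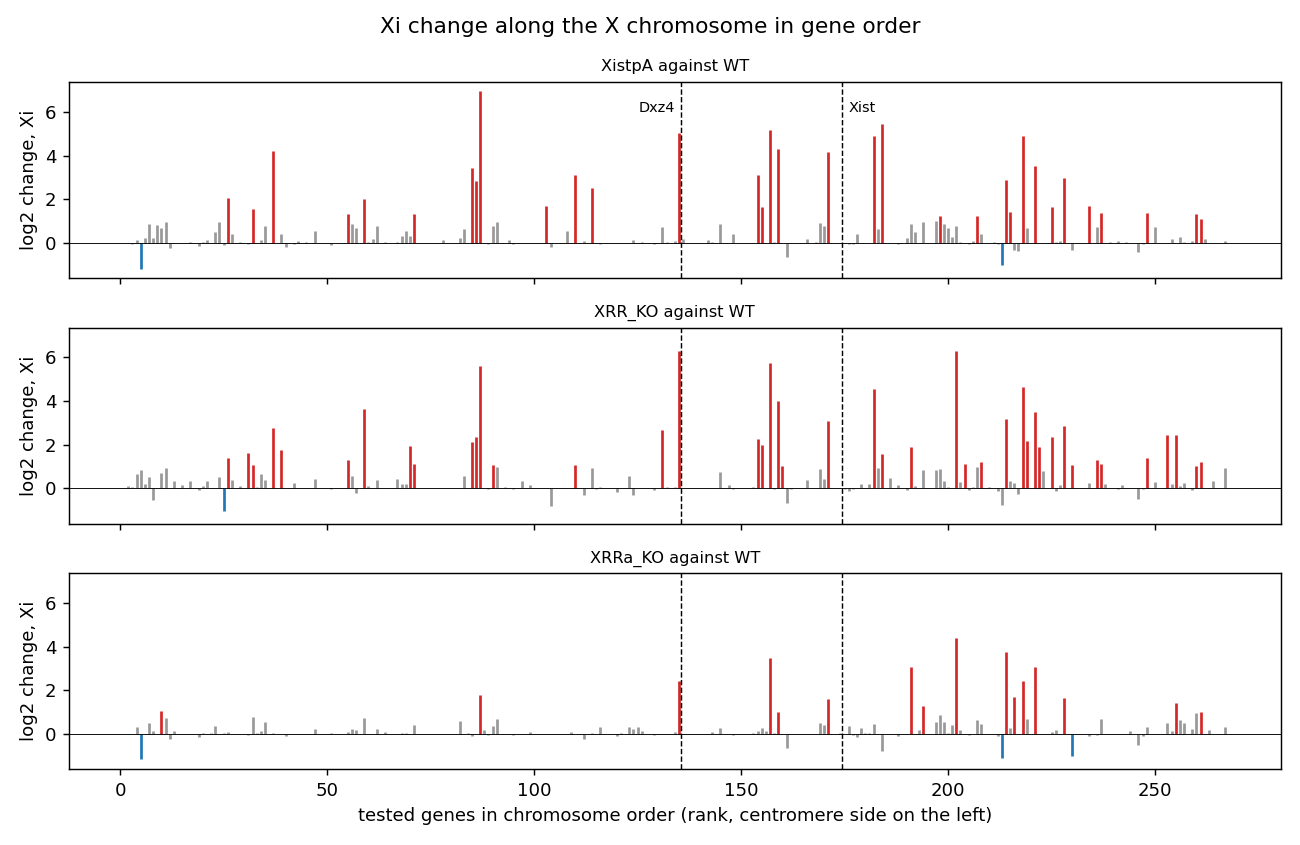
The log2 change of Xi FPKM against WT is drawn for 267 tested genes in chromosome order, without Xist and Tsix; red bars rose, blue bars fell and dashed lines mark Dxz4 and Xist. In XRRa_KO 10 of 93 genes distal of Xist rose and 3 of 135 proximal to Dxz4.

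Rises were more frequent distal of Xist and less frequent proximal to Dxz4. In XRR_KO 21 of 93 genes distal of Xist rose, at the 99.5th percentile of random gene sets, and 16 of 135 genes proximal to the Dxz4 repeat rose, at the 0.41st percentile. For XRRa_KO the figures were 10 of 93 (99.2nd) and 3 of 135 (0.21st), and for XistpA 15 of 93 (95.6th) and 13 of 135 (3.26th). The 30 tested genes nearest to Xist held 3, 4 and 1 rises in XistpA, XRR_KO and XRRa_KO, between the 28.6th and 40.1st percentile. The random sets treat neighbouring genes as independent. Under settings tried for position after the data were seen, the strength of this pattern depended on the pseudocount and the filter. In XistpA, XRR_KO and XRRa_KO, distal rises lay at the 99.4th, 99.9th and 99.995th percentile with a pseudocount of 0.1 (27, 32 and 22 of 93 genes), at the 66.9th, 93.1st and 97.9th with 1 (10, 14 and 7), and at the 63.8th, 96.3rd and 98.6th with a filter of 5 FPKM. Proximal rises lay at the 2.9th, 1.38th and 0.02nd, the 19.1st, 4.3rd and 0.83rd, and the 18.1st, 1.36th and 0.29th percentile.

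The XRRb and XRRc lines are named XaKO or XiKO in the labels, which do not describe the change, and XiKO was set against XaKO. In XRRb 5 genes rose on Xi and 0 fell. Tceal8 went from 5.46 to 38.2 FPKM (2.70), Rpl36a from 0.054 to 2.91 FPKM (2.62), Morf4l2 from 2.52 to 15.9 FPKM (2.44), Gm5643 rose by 1.06, and Hprt, a purine salvage enzyme gene, was listed at 0 and then 0.702 FPKM. Without genes that have near-identical copies, 3 rises were left, among them Gm5643, which had no transcript to check. Xist on Xi was 10.9 FPKM in XaKO and 6.72 FPKM in XiKO (-0.66). On Xa 2 genes rose (Hs6st2 and Gpc3, by 1.45 and 1.08) and 6 fell, led by Taf9b, Itm2a and Armcx1 (-3.05, -2.81 and -2.02).

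In XRRc 2 genes rose on Xi, Tceal8 to 1.83 FPKM (2.08) and Gripap1 to 0.605 FPKM from a listed 0. On Xi 4 genes fell. Cetn2 and Gm5643 were listed at 0 against 4.08 and 0.998 FPKM, and Ccdc22 and Morf4l2 fell by -1.50 and -1.35. Xist was 8.35 FPKM in XaKO and 9.74 FPKM in XiKO. On Xa 3 genes rose (Armcx1, Itm2a and Hs6st2, by 2.98, 2.02 and 1.62) and 3 fell (Tsix, 4933402E13Rik and Gpc3, by -2.04, -1.68 and -1.55). As a yardstick chosen after the data were seen, XRRb_XaKO against XRRc_XaKO gave 1 rise and 3 falls on Xi and 3 rises and 2 falls on Xa. The numbers on Xi in XRRb and XRRc were of that order. Many of the genes were also those of the XRRc contrast, with the same directions. On Xi, Tceal8 rose and Ccdc22, Cetn2 and Morf4l2 fell in both. On Xa, Armcx1 and Itm2a rose and Gpc3 and Tsix fell in both. Both contrasts use the XRRc_XaKO column, so these changes may come from that column and cannot be assigned to XiKO. Medians of escape genes other than Xist on Xi were -0.10 and -0.05, at the 0.85th and 2.6th percentile, so extreme percentiles also arise with changes this small.

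**Figure D3:**
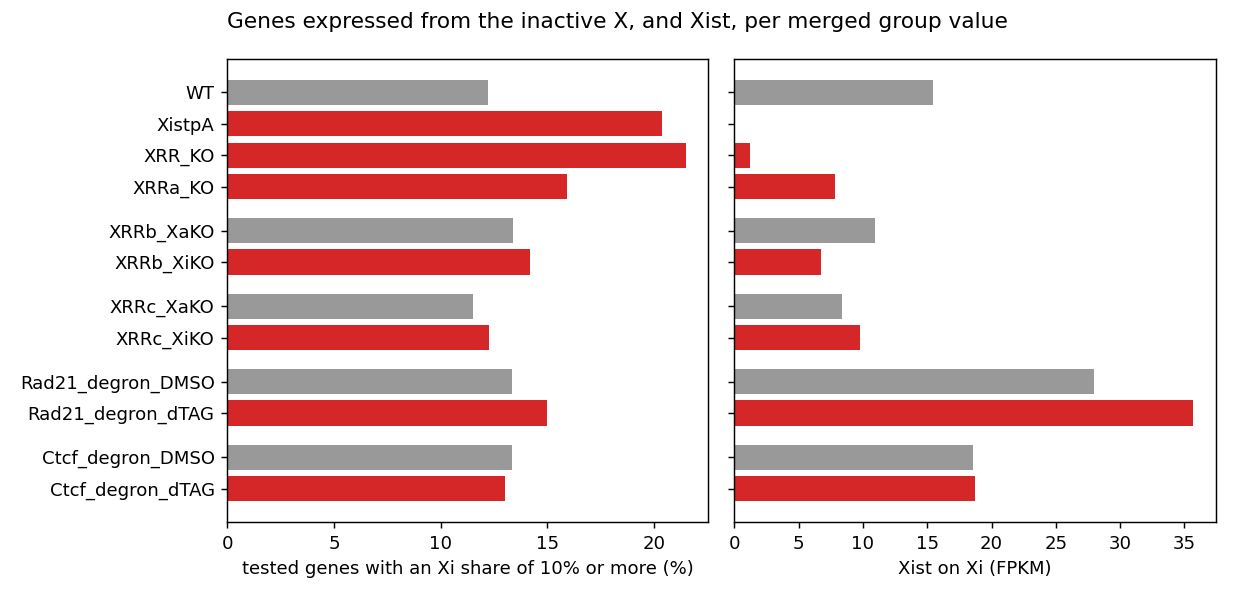
Bars give, per group, the percent of tested genes with an Xi share of 10% or more (left) and Xist FPKM on Xi (right), with grey bars for control groups and red bars for the groups compared with them; tables are set apart by WT, XRRb/XRRc, Rad21 and Ctcf, and FPKM levels should be read within a table. XistpA and XRR_KO reach 20.4% and 21.5% against 12.2% in WT, with Xist at 0 and 1.18 FPKM against 15.5 FPKM.

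Rad21 is a cohesin subunit, and its degradation was tested by dTAG against DMSO. Rad21 lies on another chromosome and was not analysed here, so these tables do not show how far it was depleted. Xist on Xi was 28.0 FPKM with DMSO and 35.6 FPKM with dTAG (0.34). On Xi 10 genes rose and 8 fell, at equal median Xa FPKM 14 rose and 5 fell, and centred on the median Xa change 17 rose and 4 fell. Eda2r rose from 0.410 to 9.42 FPKM (3.45), Ccdc120 from 0.690 to 2.83 FPKM (1.48) and Wdr45 from 6.11 to 15.2 FPKM (1.25). Upf3b, a factor of nonsense-mediated decay, Pja1, Gm6568, Tsga8 and Ngfrap1 went from a listed 0 to 3.67, 2.32, 2.61, 1.46 and 0.985 FPKM. Cited1 fell by -2.25 on Xi and by -2.19 on Xa, Nsdhl, Las1l and Ercc6l fell by -1.41, -1.09 and -1.06 on Xi, and Morf4l2, Ccdc22, Sms and Rbm3 were listed at 0 on Xi with dTAG.

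On Xa 16 of 247 genes rose and 37 fell with dTAG, with a median Xa change of -0.26. At equal median Xa FPKM 26 rose and 19 fell, and centred on the median Xa change 22 rose and 26 fell. Scaling between the columns would shift all genes alike, and whether it made the excess of falls was not tested. Itm2a rose by 2.62. Emd, Gm41 and Tsix went from a listed 0 on Xa to 6.83, 2.097 and 13.2 FPKM, and Uxt, Gm5643, Prickle3 and Ccdc22 were listed at 0 with dTAG on both alleles. Of 39 housekeeping genes, 1 rose and 5 fell on Xa, among them Timm8a1, Rbmx and Prps1 (-1.83, -1.45 and -1.17), and Ndufa1 rose on Xi by 1.22. Of 29 chromatin genes, Usp11 rose and Ercc6l, Rbmx and Hcfc1 fell on Xa, no higher a rate of falls than among all tested genes, with a list median at the 56.6th percentile. Escape genes had 2 (Utp14a and Ddx3x, -1.49 and -1.16).

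The share of escape genes on Xi does not depend on scaling between columns. Among 25 genes with a share of 10% or more in the control groups of the other tables, a set chosen after the data were seen, the Xi share was higher with dTAG for 21 and lower for 4, and the median share was 43.9% against 33.6% with DMSO. The median change was -0.08 on Xi and -0.46 on Xa. Ddx3x went from 35.0% to 48.7%, Kdm5c from 27.7% to 40%, Utp14a from 22.2% to 60.0% and Wdr45 from 25% to 59.3%. Gpkow and Clcn5 went from 59.0% to 48.4% and from 50.9% to 40%. Shares in the Rad21 table are coarse, which limits these single-gene differences. Of the genes checked under Other observations, 74.4% with DMSO and 86.0% with dTAG had shares equal to ratios of whole numbers, against 26.1% in WT. How far this affects the counts of higher and lower shares was not tested. A matching set of 24 genes in XistpA, XRR_KO and XRRa_KO had median shares of 48.8%, 48.4% and 40.8% against 32.6% in WT, higher for 21, 22 and 22 genes. Controls of other tables lay on both sides of WT for this set. XRRb_XaKO and XRRc_XaKO had medians of 36.9% and 34.7% and exceeded WT for 19 and 17 of the 24 genes. Rad21 degron with DMSO had 34.3% (13 genes higher and 11 lower than WT), and Ctcf degron with DMSO had 26.1% (7 higher and 17 lower). Counts of genes above WT therefore say little by themselves, above all for XRRa_KO. Of 26 genes in XRRb and XRRc the share was higher in XiKO for 15 and 14.

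**Figure D4:**
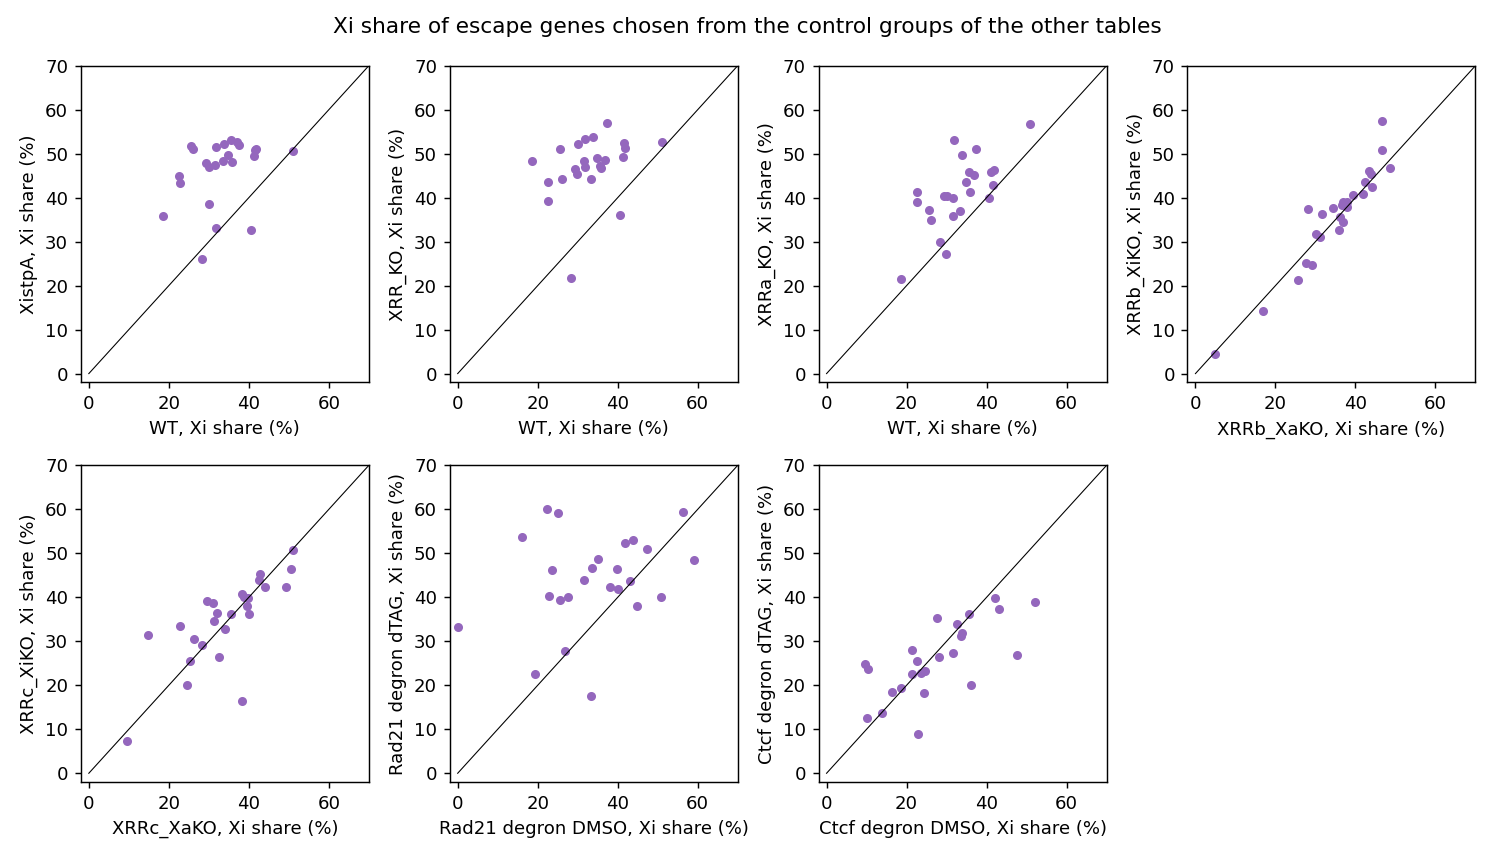
Each point is an escape gene, chosen from the control groups of the other tables, with its Xi share in the control column on the horizontal axis and in the compared group on the vertical axis; the line marks equality. Most points lie above the line in XistpA (21 of 24), XRR_KO (22 of 24), XRRa_KO (22 of 24) and Rad21 degron with dTAG (21 of 25), against 15 of 26 in XRRb, 14 of 26 in XRRc and 11 of 25 in Ctcf degron with dTAG. The control columns XRRb_XaKO and XRRc_XaKO (not drawn against WT) also exceed WT for 19 and 17 of the 24 genes, and those of Rad21 and Ctcf degron with DMSO for 13 and 7. The panels with WT and those of XRRb and XRRc therefore do not compare directly. Shares in the Rad21 panel are coarser than in the others.

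Ctcf, an architectural DNA-binding protein, was tested in the same way, and it too lies on another chromosome. Xi values hardly moved. Of 277 tested genes, only S100g rose on Xi, from a listed 0 to 0.647 FPKM, and only Praf2 fell, from 5.43 FPKM to a listed 0. Xist on Xi was 18.6 FPKM with DMSO and 18.7 FPKM with dTAG. Among 25 escape genes chosen as above, the share was higher for 11 and lower for 14, with medians of 24.7% and 25.6%. On Xa 15 genes rose and 2 fell, with a median change of 0.23, and 10 rose and 2 fell at equal median Xa FPKM. The muscle gene Fhl1 rose from 1.65 to 16.1 FPKM (2.95), 4933402E13Rik rose by 2.23, and Mageh1 and Fam3a went from a listed 0 to 2.70 and 2.56 FPKM. Ocrl fell by -1.06, and Prickle3 was listed at 0 against 10.05 FPKM. In the X inactivation centre list Nap1l2 rose on Xa (1.42), and among 15 extraembryonic genes Mageh1 and Xlr3c did (median at the 95.9th percentile). 4933407K13Rik, transcribed at Dxz4, was listed at 0 on Xi and at 1.73 and 1.92 FPKM on Xa.

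Markers of other cell types on the X were mostly unexpressed. In WT the highest neural, blood, pluripotent or germ, and muscle or mesenchyme members were Tspan7 at 6.82 FPKM, Itm2a at 1.23 FPKM, Tex13 at 13.6 FPKM and Fhl1 at 44.7 FPKM, with 2, 1, 1 and 3 members at 1 FPKM or more. Itm2a changed past the size rule in 5 of the comparisons and in both directions. Of the X-linked cohesin subunit genes 2 were tested, and neither changed by the size rule on Xi or Xa in any comparison.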

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

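The results below stand out because a gene moved past the size rule in opposite directions under the same contrast in different lines. Each rests on 1 merged value per group, and the differences were not tested. Between the XRRb and XRRc contrasts of XiKO against XaKO, the log2 changes differed by 3.78 for Morf4l2 on Xi, 2.65 for Gm5643 on Xi, -5.00 for Armcx1 on Xa, -4.83 for Itm2a on Xa and 2.64 for Gpc3 on Xa. The XaKO lines differed among themselves for Morf4l2 (2.52 FPKM in XRRb and 12.9 FPKM in XRRc), Armcx1 (7.05 and 0.371 FPKM), Itm2a (7.14 and 0.206 FPKM) and Gpc3 (9.18 and 30.4 FPKM). Between Rad21 and Ctcf degron cells, the dTAG change of Mum1l1 on Xa differed by -2.42, with values of 7.71 and 2.81 FPKM in Rad21 and 1.78 and 4.42 FPKM in Ctcf. No explanation was tested for these genes.

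The tests in the next paragraphs were all chosen after the results were seen. The first pattern is the rise of Xi FPKM in XistpA and XRR_KO. If cells with 2 active X chromosomes had been mixed in, genes silent in WT would gain Xi share alike. Of 142 genes with a WT share below 10% and at least 5 FPKM on Xa in XistpA, 81.0% stayed below a share of 1%, and 76.7% of 133 did in XRR_KO, while the risen genes among them had median shares of 22.2% and 10.6%. Reads shared with near-identical copies also do not account for the pattern, since no such copy was found for 30 of the 33 risen genes in XistpA and 38 of the 43 in XRR_KO. Gm5643, among the latter, had no transcript to align and was not checked. Differences between cell lines, the loss of Xist FPKM and the genotypes themselves all remain open, because each group is 1 merged value and WT is the only control in the table.

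The second pattern is the excess of Xa falls after dTAG in Rad21 degron cells, 37 against 16 rises. It depends on scaling: at equal median Xa FPKM 19 fell and 26 rose, and centred on the median Xa change 26 fell and 22 rose. Scaling between the columns and a broad fall of Xa expression both remain open. Rescaling moves all genes alike and so sets the balance of rises and falls itself, and no total that does not depend on these genes was at hand. Missing estimates listed as 0 are a weaker candidate explanation, since without such genes 32 still fell and 13 rose.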

How the results depend on the processing

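No paired analysis was possible because each group entered the tables as 1 merged column, and for the same reason leaving out samples in turn, a replicate block and other splits of the samples were not run. The planned windows of 5 and 10 Mb around Xist were not run either, as only gene order was used. Of 374 values under an alternative, 284 stayed within the rule for the same result and 90 moved. Where rises and falls differed in number, the larger side swapped on Xa for Rad21 at equal median Xa FPKM, for XRR_KO when centred on the median Xa change and for XRRb with a filter of 5 FPKM, and the numbers became equal on Xa for XistpA with that filter. Equal medians and centring move all genes alike, so they set that balance and do not test it. At equal median Xa FPKM the median Xa change moved from -0.26 to 0.10 for Rad21, from 0.23 to -0.01 for Ctcf, from -0.19 to -0.05 in XRR_KO and from -0.09 to 0.03 in XRRb. The choices of leaving out genes with copies, genes listed at 0 on Xa or Rps4x, of the mean for lists, of centring and of other settings for position along X were made after seeing the data. In every comparison with WT, Xi rises outnumbered Xi falls under each setting run. Genes listed at 0 on Xi in WT could rise but not fall, so this balance was partly set in advance. Among genes with 1 FPKM or more on Xi in both columns, 9 rose and 0 fell in XistpA. In XRR_KO 10 of such genes rose and 2 fell, and in XRRa_KO 6 rose and 0 fell. FPKM without read totals limits what can be said of genes near 0, where the pseudocount sets the size of a change. The causes of the shifts below were not tested, except that a filter changes the number of genes tested.

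With a pseudocount of 0.1, Xi rises numbered 58 in XistpA, 69 in XRR_KO, 33 in XRRa_KO, 12 in XRRb, 8 in XRRc, 18 for Rad21 and 6 for Ctcf, and Xi falls numbered 6 in XRR_KO, 6 in XRRa_KO, 4 in XRRb, 11 in XRRc, 16 for Rad21 and 6 for Ctcf, while 2 genes rose on Xa in XRRa_KO. With a pseudocount of 1, Xi falls were 2 in XistpA, 0 in XRRa_KO and 3 for Rad21, Xi rises were 3 in XRRb, 1 in XRRc and 0 for Ctcf, and on Xa 1 gene rose in XRR_KO and 1 fell for Ctcf. With no filter, Xa rises were 5 in XRR_KO, 4 in XRRa_KO and 4 in XRRb, Xa falls were 2 in XRRa_KO, 9 in XRRc and 4 for Ctcf, and Ctcf had 2 Xi rises. With a filter of 5 FPKM, Xa rises were 1 in XistpA, 1 in XRR_KO, 0 in XRRa_KO, 1 in XRRc, 7 for Rad21 and 5 for Ctcf, Xa falls were 1 in XistpA, 0 in XRRa_KO, 0 in XRRb and 1 for Ctcf, and XRRc had 1 Xi rise. At equal median Xa FPKM, 6 genes rose on Xa in XRR_KO, 26 rose and 19 fell on Xa for Rad21, and 5 fell on Xi for Rad21. Centred on the median Xa change, 7 genes rose and 4 fell on Xa in XRR_KO, 17 rose and 4 fell on Xi for Rad21, and 0 rose on Xi for Ctcf. Without genes that have near-identical copies 3 genes rose on Xi in XRRb, and without genes listed at 0 on Xa 1 gene fell on Xa for Ctcf.

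The difference in median Xi share was 0.029 points in XistpA and 0.079 points in XRR_KO, and 0 in the other comparisons. It was 0 in both with no filter and 0.071 and 0.13 points with a filter of 5 FPKM. Taken as the share of summed FPKM without Xist and Tsix, the difference was 8.50 points in XistpA, 9.79 in XRR_KO, 5.28 in XRRa_KO, 0.826 in XRRb, 0.020 in XRRc, 2.83 for Rad21 and -1.76 for Ctcf. Also without Rps4x it was 5.83, 7.42, 4.62, 0.511, 0.013, 1.76 and -0.921 points in the same order. Genes at a share of 10% or more numbered 92 in XRR_KO, 55 with DMSO and 63 with dTAG in Rad21 cells with no filter, and 24 with dTAG in Rad21 cells with a filter of 5 FPKM. The number of lists with an Xi median in the outer 5% of random lists was 2 in XistpA, XRRa_KO and Rad21 and 1 in XRRb. It was 1 in XistpA and XRRa_KO with a pseudocount of 0.1. Without escape genes it was 1 in XistpA, 0 in XRRa_KO, 0 in XRRb and 1 for Rad21, and by list means it was 1, 1, 2 and 0. Xi rises proximal to Dxz4 and distal of Xist numbered 25 and 27 in XistpA, 30 and 32 in XRR_KO and 8 and 22 in XRRa_KO with a pseudocount of 0.1, and 9 distal ones were left in XistpA with a filter of 5 FPKM.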

Other observations

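The adjacency counts, the share check of whole-number ratios and the test of runs of adjacent genes were chosen after the data were seen. Genes expressed from Xi in WT lay next to each other more often than random sets. Of 31 such genes placed in order, 10 pairs were adjacent among tested genes, against a random median of 3 (99.99th percentile). The pairs included Upf3b with Nkap, Nkap with Ndufa1, Ercc6l with Rps4x, and Mbtps2 with Yy2. Rps4x is uncertain because of its near-identical copies. Whether paired genes overlap was not checked, and in unstranded libraries the reads of overlapping genes cannot be told apart. The Ctcf table listed 53 genes that the other tables did not, and 51 of them lay distal to every other listed gene. In that block Piga and Zrsr2 had Xi shares of 26.7% and 30.4% with DMSO and 32.4% and 24.8% with dTAG.

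The third pattern is that Xi rises in XRR_KO and XRRa_KO lay more often distal of Xist. A hypothesis is that 1 run of adjacent genes makes up the excess, tested after the pattern was seen. In XRRa_KO, 10 distal genes rose against a random median of 5, and the longest run of adjacent risen genes there was 1. In XRR_KO, 21 rose against a random median of 14, and the longest run was 2, with 4 adjacent pairs where random orders had a median of 4. Runs this short argue against a single run of adjacent genes past the size rule as the source of the excess of 5 and 7 genes. The distal excess also depended on settings, chosen after the data were seen. With a pseudocount of 0.1 it was at the 99.9th percentile in XRR_KO and 99.995th in XRRa_KO, with a pseudocount of 1 at the 93.1st percentile in XRR_KO and 97.9th in XRRa_KO, and with a filter of 5 FPKM at the 96.3rd and 98.6th. A biological cause of the distal excess was not tested.

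Of 9 genes that rose on Xi in Rad21 degron cells with dTAG and were tested in both tables, 3 had also risen in XistpA or XRR_KO (Eda2r, Pja1 and Upf3b), where independent lists would share 1.69.

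The Xa and Xi values of many genes stood in ratios of small whole numbers. Among genes with a share between 1% and 99%, the share equalled a fraction with a denominator of 100 or less, within 5e-06, for 74.4% of genes with DMSO and 86.0% with dTAG in the Rad21 table, 26.1% in WT, 30.3% in XRRa_KO, 6.0% and 4.08% in the Ctcf table and 0% in XistpA. Shifting the shares at random by up to 1% left 2.67% to 3.74%. No counts were derived from these ratios. Shares in the Rad21 table are therefore coarser than in the others, and differences in share between single genes there should be read with that in mind.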
